A study of Caenorhabditis elegans with 23 samples.

How the data were processed

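Expression was measured in whole-worm RNA of 23 samples, each hybridised to 1 array after biotin labelling, per the labels' protocols. The deposited values are log2 intensities per probe set made with RMA per the submitters' processing notes. The software version and the chip definition are not given in the sources used here. The log2 scale was checked on the values, and L3 and day 8 arrays have separate median levels (5.72 to 5.91, and 4.89 to 5.01), so the ages look to have been normalized apart. The submitters left out the day 8 WT EV array number 3 for quality, per the labels, so that group has 2 arrays. Mean correlation across probe sets of an array with the others of its group lay between 0.983 and 0.997, and the SD of the difference between 2 arrays of a group between 0.142 and 0.439. The number of arrays limits the precision.

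The 22548 probe sets were taken as deposited, with 6 empty cells in 5 probe sets and no other filter. Gene names came from the platform annotation, and 20701 probe sets got a current symbol through the reference gene table (assembly WBcel235). Of all probe sets 20766 name 1 gene, 887 several and 895 none, which gives 17116 genes. Probe sets whose names end in _s_at or _x_at (6711) can bind several transcripts and are called shared, and a gene named on one is uncertain.

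Comparisons were fitted with limma 3.58.1 in R 4.3.3 on the deposited values, with a mean per group, default empirical Bayes settings and two-sided tests. Each age was fitted apart (12 and 11 arrays), except for contrasts between ages, which used all 23 arrays. P-values were adjusted by Benjamini and Hochberg over all probe sets tested in a comparison, and a probe set is said to rise or fall where its adjusted p is under 0.05. The contrasts were ash-2 RNAi against EV in each genotype and age, glp-1 against WT under EV at each age, day 8 against L3 under EV in each genotype, the RNAi by genotype interaction at each age (the change in WT minus that in glp-1), and the RNAi by age interaction in WT (the change on day 8 minus that at L3). Errors given with ± are standard errors of limma's log2 changes from the spread shared by the groups of a fit.

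The 23 gene lists, fixed by name, cover the H3K4 methylation complex, germline proliferation and meiosis, P granules, oocytes, sperm, DNA replication, early embryonic genes, histones, yolk proteins, somatic gonad, fatty acid metabolism, DAF-16 and germline-less longevity targets, innate immunity, detoxification, chaperones, collagens, moulting, vulva, muscle, neurons, intestine, ribosomal proteins and the respiratory chain. Each was tested with camera from limma against all other genes, with the brightest probe set per gene, a preset correlation of 0.01 and adjustment over the lists of a comparison. The test was repeated with an estimated correlation, and with fry, which tests whether a list's genes move one way (or, mixed, either way) without comparing them with other genes. Numbers of lists passing with the preset correlation, the estimated correlation, fry and fry mixed were 10, 2, 2 and 7 for ash-2 RNAi in L3 WT, 11, 0, 4 and 9 for ash-2 RNAi in L3 glp-1, 7, 0, 0 and 12 for ash-2 RNAi in day 8 WT, 11, 0, 7 and 22 for ash-2 RNAi in day 8 glp-1, 11, 0, 0 and 2 for the L3 interaction and 12, 0, 1 and 19 for that on day 8. Members were counted with p adjusted over all probe sets and adjusted over the list alone. Germline-dependent probe sets were those lower in glp-1 under EV by at least 2-fold at the other age.

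Genes are named by a rule: per comparison ash-2, the 8 largest rises and 8 largest falls among passing probe sets of 1 gene whose groups do not overlap (a condition dropped for interactions), the 4 smallest p where none pass, and from each list that shifted or had at least 3 members passing, the 4 members with the smallest p, with all yolk and H3K4 genes. The text gives a selection of these. Of those named and passing in the ash-2 comparisons, 2 of 22 in L3 WT, 13 of 29 in L3 glp-1, 14 of 45 in day 8 WT and 13 of 94 in day 8 glp-1 no longer passed when some 1 array was left out. The text names utx-1, pat-10 and unc-52 of these, and asah-2 and F19C7.2 in day 8 WT were not tested that way. The comparisons, tests, lists, rule and most alternatives were fixed before the data were examined.

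The steps were tested on simulated data with 200 of 22543 probe sets changed, 50 each at log2 0.5, 1, 2 and 4. For L3 WT, 27, 48, 50 and 49 of these were recovered with 8 false calls, and for day 8 WT, with 1 array fewer, 11, 35, 49 and 50 with 8 false calls. Alternatives were a 1.5-fold minimum, quantile normalization, centring on each array's median or on muscle and neuron genes, leaving out the dimmest 40 percent of probe sets or the shared ones, the mean of a gene's probe sets, trend and robust settings, array weights, replicate number as a block, an unequal variance test, other sets of arrays in the fit and leaving out each array in turn. Pairing was checked by correlating residuals of same-numbered arrays across probe sets: only L3 WT had all 3 pairs over 0.1 (0.245, 0.142 and 0.487). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.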

Results

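Transcript levels were measured in whole worms of Caenorhabditis elegans on 23 single-sample arrays. Worms were wild type (WT, strain N2) or glp-1(e2141ts), a temperature-sensitive mutant of the Notch receptor that germline stem cells need, which per the labels forms few germ cells. They had been treated with RNAi against ash-2, which encodes a subunit of the complex that methylates histone H3 at lysine 4 (H3K4), or with the empty vector (EV). Worms were collected at a stage labelled L3, an age at which per the labels H3K4 methylation had changed, and on day 8, in mid-life. The 8 groups hold 3 arrays each, except day 8 WT EV with 2, and the labels give growth at 20 degrees for all of them. Whether the glp-1 worms were kept at a restrictive temperature is not stated. Below, EV 1 is EV replicate 1. The labels do not say whether the arrays of a group come from separate cultures, so they may be technical replicates. The comparisons ask which genes depend on ash-2 at each age and whether that dependence needs an intact germline.

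The target of the RNAi was read first, since it checks the labels. In the arrays labelled ash-2 RNAi, 3 of the 4 ash-2 probe sets (171772, 172463 and 172493, all shared) lay far above EV and the other, 175434, lay below it. The 3 shared probe sets rose by 5.91, 6.54 and 6.93 on the log2 scale in L3 WT and by 6.45, 6.48 and 6.91 in L3 glp-1. On day 8 they rose by 4.54, 4.70 and 5.01 in WT and by 7.09, 7.97 and 8.29 in glp-1, and in every group all arrays labelled ash-2 RNAi lay above all EV arrays. Probe set 175434 fell in day 8 WT by 1.82 (95% interval −2.16 to −1.48, adjusted p = 2.35e-04, n = 3 against 2). Its changes in L3 WT (−0.33, interval −0.55 to −0.12, adjusted p = 0.343), L3 glp-1 (−0.24, interval −0.45 to −0.021, adjusted p = 0.345) and day 8 glp-1 (−0.40, interval −0.71 to −0.098, adjusted p = 0.0786) did not pass over all probe sets. The L3 WT change passed with replicate number as a block and the 6 L3 WT arrays alone (−0.33, adjusted p = 0.0470, an alternative chosen after seeing the data). It also passed with array weights (−0.34, adjusted p = 0.0470). Pairing of these arrays by number is not clearly shown. In day 8 glp-1 the change of 175434 ranged from −0.51 to −0.28 with 1 array left out, passing only without EV 3 (−0.51). In the day 8 glp-1 arrays labelled ash-2 RNAi an ash-2 probe set has the highest value of the array (14.74, 14.88 and 14.90), so saturation is not excluded and the sizes of the rises and of their differences are uncertain. The cloned RNAi sequence is not given, so a probe set inside it does not check the labels. Directions below are therefore those of the arrays labelled ash-2 RNAi against those labelled EV.

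**Figure D1:**
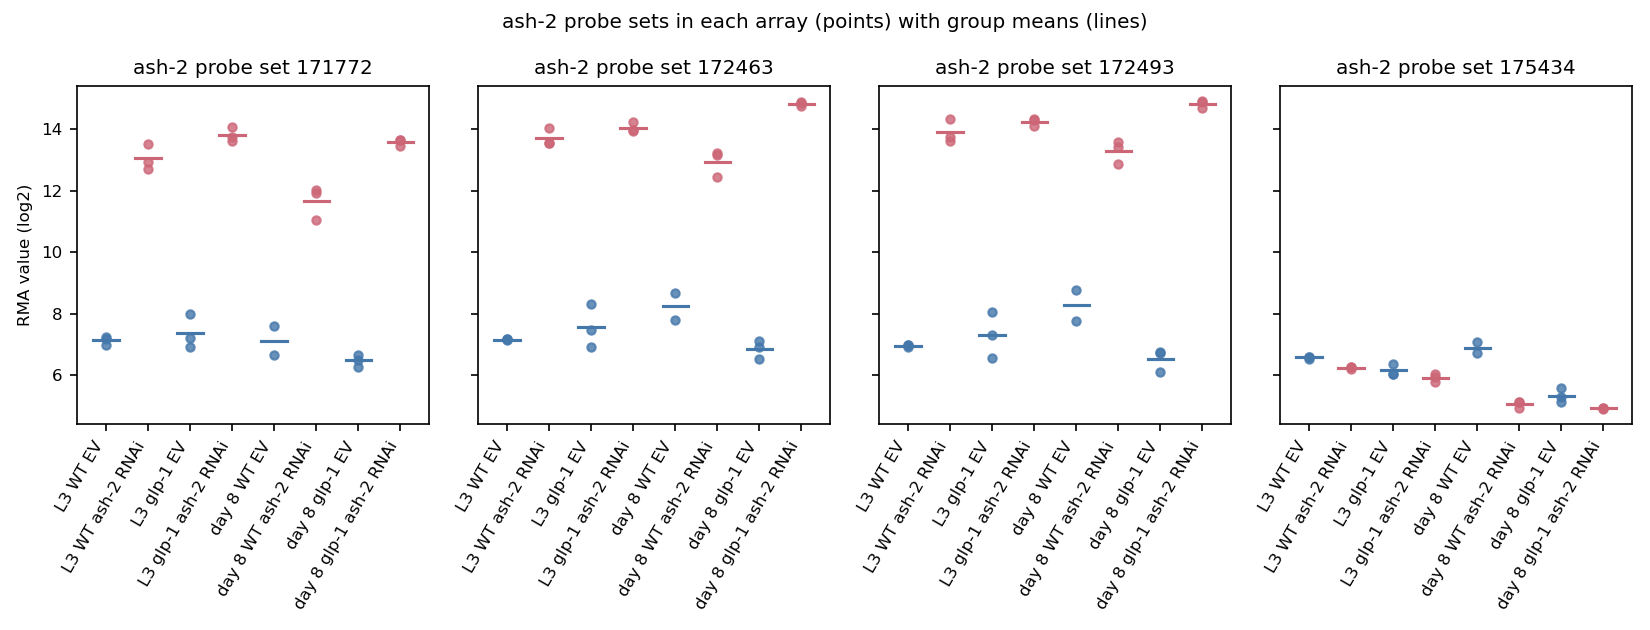
RMA value (log2) of the 4 ash-2 probe sets by group, with a point for each of the 23 arrays and a line for each group mean. The 3 shared probe sets lie higher in every group labelled ash-2 RNAi, by 4.54 to 8.29, and 175434 changes by −0.24 in L3 glp-1 to −1.82 in day 8 WT.

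In L3 WT small heat shock genes and an insulin-like gene were among the largest rises with ash-2 RNAi, and single lectin and infection response genes were among both the rises and the falls. The heat shock genes hsp-16.41 (2.04 ± 0.16) and hsp-16.2 (1.73 ± 0.12), the C-type lectin genes clec-17 (2.00 ± 0.13) and clec-174 (1.90 ± 0.16), the insulin-like gene ins-35 (1.65 ± 0.14) and the infection response gene irg-5 (0.92 ± 0.09) rose (log2 change ± SE, n = 3 against 3, adjusted p from 3.79e-06 to 2.71e-04). Genes that fell included irg-1 (−1.66 ± 0.13), clec-67 (−1.63 ± 0.13), Y58A7A.5 (−1.43 ± 0.13) and F19C7.2 (−1.21 ± 0.08), the ABC transporter gene pgp-5 (−1.33 ± 0.19), the acid sphingomyelinase gene asm-2 (−1.22 ± 0.14), K11H12.4 (−1.31 ± 0.18) and the glucuronosyltransferase gene ugt-26 (−1.11 ± 0.11) (largest adjusted p = 0.00601). By the rule that named these genes, all arrays of one group lay above all arrays of the other. The values of clec-17, clec-174, pgp-5, K11H12.4 and asm-2 come from shared probe sets. Of the 22548 probe sets tested, 74 passed, 49 up and 25 down, in 54 genes, and 24 of them changed at least 2-fold.

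Histone genes lay higher as a set in L3 WT. Of 26 measured, 4 rose, 0 fell and 22 did not pass, or 13 and 0 adjusted over the list alone. The list median was 0.28 (adjusted p = 9.04e-18, adjusted p = 0.0211 with an estimated correlation), with his-4 (0.89 ± 0.09), his-39 (0.80 ± 0.10) and his-1 (0.57 ± 0.08) on shared probe sets among the risers. Of 39 DAF-16 and germline-less longevity targets, 2 rose, 0 fell and 37 did not pass, or 5 and 0 adjusted over the list alone. The median was 0.11 (turning to −0.01 with muscle and neuron centring, adjusted p = 1.08e-08, adjusted p = 0.00231 with an estimated correlation), and the members that rose were the hsp-16 genes above. Of the germline lists 4 lay lower, although 0 members passed in any of them. Their medians were −0.17 for 36 germline proliferation and meiosis genes, −0.21 for 41 P granule and germline RNA genes, −0.35 for 25 oocyte genes and −0.14 for 54 DNA replication genes. Their adjusted p were 2.16e-05, 1.15e-07, 2.28e-05 and 1.90e-05, and with an estimated correlation the adjusted p were 0.193, 0.265, 0.489 and 0.489. Adjusted over the list alone, 2 P granule genes fell. The 5 yolk protein genes lay lower too (median −0.55, adjusted p = 9.46e-07, adjusted p = 0.193 with an estimated correlation), with 0 passing over all probe sets and 5 falling adjusted over the list alone. The value of vit-1 was −1.22 ± 0.30 (adjusted p = 0.165). The fit with replicate number as a block and these 6 arrays alone, chosen after seeing the data, changes these calls. In it zim-2 (−0.56), zim-3 (−0.38), mex-1 (−0.73), mes-4 (−0.46), perm-2 (−0.57), perm-4 (−0.54), egg-3 (−0.54) and all 5 yolk genes fell, the moulting genes acn-1 (0.45), grl-10 (0.67) and mlt-9 (0.51) rose (mex-1, mes-4, perm-2, perm-4, egg-3, vit-4, vit-5, vit-6 and mlt-9 on shared probe sets), and the innate immune test was lost (adjusted p = 0.0716). In the unpaired fit no moulting or neuron gene passed, but both lists lay higher. The moulting list had 53 measured (median 0.23, adjusted p = 8.98e-11, adjusted p = 0.193 with an estimated correlation). The neuron list had 67 measured (median 0.09, moved to −0.03 by construction with muscle and neuron centring, adjusted p = 1.75e-04, adjusted p = 0.136 with an estimated correlation). Of 68 innate immune genes, 2 rose, 3 fell and 63 did not pass, or 5 and 11 adjusted over the list alone. Together they had a median of −0.04 (adjusted p = 0.0342, adjusted p = 0.278 with an estimated correlation), and the test was lost without L3 WT EV 3 (−0.03) and L3 WT ash-2 RNAi 3 (−0.04). Of 73 detoxification genes, 1 rose, 1 fell and 71 did not pass, or 4 and 4 adjusted over the list alone (adjusted p = 0.904). Median and mean differed in sign for the H3K4 list (−0.03 and 0.38, adjusted p = 0.571), in which ash-2 alone passed. With an estimated correlation 2 of the 10 list tests held.

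The count in L3 WT was 44, 39 and 44 without EV 1, 2 and 3, 40, 45 and 50 without ash-2 RNAi 1, 2 and 3, and an unequal variance test called 0 where limma had 1543 at an unadjusted p under 0.05. With replicate number as a block the count was 95, and 711 with these 6 arrays alone, though pairing by number is not clearly shown. Muscle and neuron centring, which shifts the median of all probe sets by −0.12, gave 82 (22 up, 60 down).

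In L3 glp-1 several of the same genes responded. The lectin genes clec-174 (2.1 ± 0.16) and clec-17 (1.85 ± 0.13), the insulin-like gene ins-35 (1.45 ± 0.14), Y39G8B.7 (1.42 ± 0.21), the heat shock genes hsp-16.41 (1.27 ± 0.16) and hsp-16.2 (0.98 ± 0.12) and irg-5 (0.79 ± 0.09) rose (n = 3 against 3, adjusted p from 9.77e-06 to 0.00972). Genes that fell included sdz-6 (−1.21 ± 0.14) and F19C7.2 (−1.16 ± 0.08), the sphingomyelinase gene asm-2 (−1.13 ± 0.14), Y70C5A.3 (−1.09 ± 0.10) and clec-67 (−1.05 ± 0.13) and the claudin-like gene clc-12 (−0.97 ± 0.14) (largest adjusted p = 0.00972). The values of clec-17, clec-174, asm-2 and Y70C5A.3 come from shared probe sets. In total 180 probe sets passed, 67 of them down, in 161 genes, with 22 up and 5 down at least 2-fold. Most passing probe sets rose, but with median centring 89 of 212 did, and the up and down counts were 65 and 95 with muscle and neuron centring.

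Germline lists lay higher with ash-2 RNAi in L3 glp-1, and those of meiosis, P granules, oocytes and DNA replication had lain lower in WT. Of 55 sperm genes, 1 rose, 0 fell and 54 did not pass, or 2 and 0 adjusted over the list alone. As a list they had a median of 0.23 (adjusted p = 3.21e-13, adjusted p = 0.495 with an estimated correlation). Of 54 DNA replication genes 0 passed, also adjusted over the list alone. Their median was 0.19 (adjusted p = 8.07e-07, adjusted p = 0.495 with an estimated correlation). The medians were 0.12 for germline proliferation and meiosis, 0.15 for P granules and 0.32 for oocyte genes, with adjusted p of 0.00807, 7.93e-04 and 0.00459, adjusted p = 0.495, 0.557 and 0.725 with an estimated correlation. Members that rose numbered 0, 1 and 0, and 4, 1 and 0 adjusted over the list alone. Without ash-2 RNAi 2 the meiosis, P granule and oocyte tests were lost (0.07, 0.07 and 0.12), and the oocyte test also without EV 3 (0.11) or ash-2 RNAi 3 (0.21). For the mean of the meiosis and P granule lists ash-2 RNAi 1 lay lowest of the 6 arrays (5.66, against 6.15 and 6.30 in the others of its group), and 6 of the 9 pairs of arrays lay higher under ash-2 RNAi. Of 26 histone genes, 3 rose, 0 fell and 23 did not pass, or 8 and 0 adjusted over the list alone. The list median was 0.17 (adjusted p = 2.53e-07, adjusted p = 0.163 with an estimated correlation). Of 39 DAF-16 and longevity targets, 3 rose, 0 fell and 36 did not pass, or 7 and 1 adjusted over the list alone. The median was 0.03 (turning to −0.01 with median centring and −0.03 with muscle and neuron centring, adjusted p = 0.00870, adjusted p = 0.107 with an estimated correlation). Of 68 innate immune genes, 2 rose, 7 fell and 59 did not pass, or 3 and 16 adjusted over the list alone. Together they had a median of −0.15 (adjusted p = 5.03e-05, adjusted p = 0.107 with an estimated correlation). The H3K4 list (2 and 0 of 16 rose and fell, or 2 and 0 adjusted over the list alone, median 0.06, turning to −0.00031 with muscle and neuron centring, adjusted p = 0.00807, adjusted p = 0.326 with an estimated correlation) lost its test without ash-2 RNAi 2 (0.03) and without ash-2 as a member (0.04, adjusted p = 0.134, an alternative chosen after seeing the data). Its risers were ash-2 itself and utx-1 (0.58 ± 0.12), which did not pass without each of 5 arrays. The collagen list (2 and 0 of 145, or 2 and 1 adjusted over the list alone, median −0.05, adjusted p = 0.0196, adjusted p = 0.795 with an estimated correlation) lost it without L3 glp-1 EV 1 and 2 (−0.02 and −0.06) and L3 glp-1 ash-2 RNAi 2 (−0.02), and the intestine list (0 of 33 passing, median −0.09, adjusted p = 0.00807, adjusted p = 0.495 with an estimated correlation) without L3 glp-1 EV 2 (−0.11) and L3 glp-1 ash-2 RNAi 3 (−0.06).

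None of the 11 list tests held with an estimated correlation. The count of probe sets was 65 and 80 without EV 1 and 2, 307 and 47 without ash-2 RNAi 1 and 3, within 1.5-fold of 180 without the others, 25 with only these 6 arrays in the fit and 0 with an unequal variance test, against 2826 at an unadjusted p under 0.05 with limma.

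The difference between WT and glp-1 in the response to ash-2 RNAi was tested directly at L3. No single probe set passed that test (limma, smallest adjusted p = 0.369, 1859 at an unadjusted p under 0.05), but 11 of the 23 gene lists did. With an estimated correlation 0 of the 11 held, at adjusted p from 0.284 to 0.657. The genes with the smallest p, none passing, were the kinesin gene zen-4 (−0.76 ± 0.13), the anillin gene ani-1 (−0.98 ± 0.17), F36A4.4 (−0.80 ± 0.15) and F36H12.5 (−0.67 ± 0.12) (change in WT minus change in glp-1, all with adjusted p = 0.369; zen-4 and F36H12.5 on shared probe sets). Lower in WT than in glp-1 were the lists of meiosis (−0.29), P granule (−0.39), oocyte (−0.70), sperm (−0.28), DNA replication (−0.27) and yolk protein genes (−0.79), with adjusted p of 2.75e-07, 1.22e-10, 1.73e-07, 2.20e-12, 3.01e-12 and 7.45e-06. Adjusted over the list alone, 3 P granule and 5 yolk protein genes differed. The moulting list lay higher in WT (median 0.22, adjusted p = 5.21e-05). Histone (0.13), DAF-16 target (0.10), collagen (0.10) and neuron genes (0.11) lay higher too, with adjusted p of 0.0461, 0.0474, 0.00364 and 0.0347..

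Without glp-1 EV 3 the medians of yolk (−0.45), oocyte (−0.41) and moulting genes (0.11) in this difference shrank more than 1.5-fold, as did that of sperm genes without glp-1 EV 2 (−0.17). Oocyte and DNA replication genes had −1.31 and −0.43 without glp-1 ash-2 RNAi 1. The histone test was lost without WT EV 1 and 2 (0.13 and 0.11), WT ash-2 RNAi 1, 2 and 3 (0.11, 0.15 and 0.11), glp-1 EV 2 and 3 (0.12 and 0.10) and glp-1 ash-2 RNAi 1 and 3 (0.11 and 0.09), and the DAF-16 target test without WT EV 1 and 3 (0.09 and 0.10), WT ash-2 RNAi 1 and 2 (0.10 and 0.10), glp-1 EV 1 and 2 (0.09 and 0.11) and glp-1 ash-2 RNAi 1, 2 and 3 (0.08, 0.09 and 0.08). The collagen test was lost without WT EV 3 (0.10), WT ash-2 RNAi 1 and 2 (0.08 and 0.08) and glp-1 ash-2 RNAi 2 (0.05), and the neuron test without WT EV 3 (0.09), WT ash-2 RNAi 2 (0.09), glp-1 EV 3 (0.05) and glp-1 ash-2 RNAi 1 (0.07). The count of probe sets was 62 without glp-1 ash-2 RNAi 1 and 11 without glp-1 ash-2 RNAi 2. The calls of the separate comparisons overlapped: 17 probe sets rose in both genotypes against 0.246 by chance, 12 fell in both against 0.0743, and 0 moved in opposite directions. Across probe sets, which are not independent replicates, the changes correlated with r = 0.261 and rho = 0.0252, or r = 0.112 without those of ash-2, and the comparisons share no arrays.

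**Figure D2:**
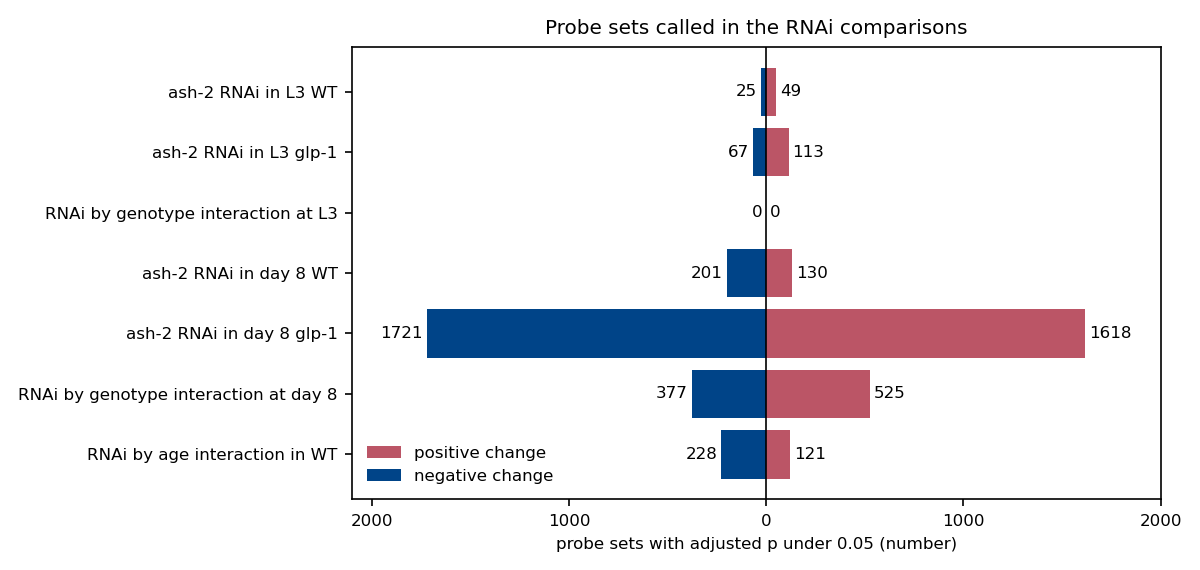
Number of probe sets with adjusted p under 0.05 in the ash-2 RNAi comparisons and interactions, positive changes to the right of 0 and negative ones to the left. Ash-2 RNAi changed 74 and 180 probe sets at L3 in WT and glp-1 and 331 and 3339 on day 8, and the directions shift with centring.

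On day 8 in WT a flavin monooxygenase gene was among the largest falls with ash-2 RNAi and a saposin-like gene and small heat shock genes among the largest rises. The monooxygenase gene fmo-2 fell by 4.60 ± 0.21, from 9.66 to 5.06 (n = 3 against 2, adjusted p = 2.62e-06). Further falls were T22F3.11 (−3.94 ± 0.16), the alcohol dehydrogenase gene adh-1 (−3.72 ± 0.48), C23G10.11 (−3.03 ± 0.26), the lysozyme gene ilys-5 (−2.87 ± 0.23), the bestrophin gene best-1 (−2.63 ± 0.23), C35C5.8 (−2.48 ± 0.24) and the acyl-CoA synthetase gene acs-2 (−2.31 ± 0.31) (largest adjusted p = 0.00413). The saposin-like gene spp-12 (4.83 ± 0.54), clec-174 (3.19 ± 0.20), irg-5 (2.63 ± 0.24) and srlf-30 (2.49 ± 0.17), the heat shock genes hsp-16.41 (2.46 ± 0.34) and hsp-16.2 (2.41 ± 0.20) and dod-6 (2.29 ± 0.23) rose (largest adjusted p = 0.00515). By the rule that named these genes, all arrays of one group lay above all arrays of the other. The values of ilys-5, clec-174 and dod-6 come from shared probe sets. The lower quartile of the EV arrays is 3.96 and 4.0, and spp-12 in EV (4.19) and T22F3.11 and C35C5.8 under ash-2 RNAi (both 4.33) lie near it, so the sizes of changes from or to such low values are uncertain. In total 331 probe sets passed, 130 up and 201 down, in 285 genes, and 199 changed at least 2-fold.

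Of 63 fatty acid metabolism genes, 3 rose, 6 fell and 54 did not pass, or 8 and 9 adjusted over the list alone, without a shift of the list (adjusted p = 0.410). The hydroxyacyl-CoA dehydrogenase gene hacd-1 (−1.73 ± 0.15), the glyoxylate cycle gene icl-1 (−1.43 ± 0.16) and the lipase gene lipl-5 (−1.1 ± 0.17) fell, and the desaturase gene fat-5 (1.02 ± 0.13) rose. Of 68 innate immune genes, 4 rose, 8 fell and 56 did not pass, or 6 and 11 adjusted over the list alone (adjusted p = 0.238), with spp-1 (−1.71 ± 0.15) among those that fell. Of 39 DAF-16 and longevity targets, 5 rose, 2 fell and 32 did not pass, or 7 and 3 adjusted over the list alone (adjusted p = 0.113). Of 73 detoxification genes, 8 rose, 0 fell and 65 did not pass, or 10 and 1 adjusted over the list alone. As a list they had a median of 0.09 (turning to −0.08 with muscle and neuron centring, adjusted p = 1.07e-04, adjusted p = 0.236 with an estimated correlation), with ugt-63 (1.97 ± 0.30) among them. Of 145 collagen genes, 7 rose, 0 fell and 138 did not pass, or 17 and 0 adjusted over the list alone. Their median was 0.13 (turning to −0.04 with muscle and neuron centring, adjusted p = 2.05e-07, adjusted p = 0.509 with an estimated correlation). Of 44 muscle genes, 4 rose, 1 fell and 39 did not pass, or 11 and 1 adjusted over the list alone. The median was 0.15 (moved to −0.02 by construction with muscle and neuron centring, adjusted p = 3.93e-06, adjusted p = 0.509 with an estimated correlation). Of 33 intestinal genes, 2 rose, 5 fell and 26 did not pass, or 4 and 9 adjusted over the list alone. The median was −0.12 (adjusted p = 0.00454, adjusted p = 0.509 with an estimated correlation), and those that fell included the cathepsin B-like genes cpr-1 (−1.53 ± 0.14) and cpr-6 (−1.06 ± 0.12) and the nuclease gene nuc-1 (−1.44 ± 0.15). Of 53 moulting genes, 0 rose, 3 fell and 50 did not pass, or 1 and 8 adjusted over the list alone. Together they had a median of −0.07 (adjusted p = 0.00454, adjusted p = 0.509 with an estimated correlation). No yolk protein gene passed, or 3 adjusted over the list alone. As a list they had a median of −0.47 (adjusted p = 1.07e-04, adjusted p = 0.509 with an estimated correlation). No ribosomal protein gene passed (median 0.05, turning to −0.12 with muscle and neuron centring and no longer passing, adjusted p = 0.0364, adjusted p = 0.703 with an estimated correlation). The intestine and yolk tests were lost without EV 1 (0.02 and −0.31), the moulting and ribosomal tests without EV 2 (−0.08 and 0.05), and the ribosomal test without ash-2 RNAi 1 or 3 (0.04 and 0.05). The probe sets of icl-1 and spp-1 are shared. Median and test differed in sign for the H3K4 (−0.02, adjusted p = 0.553) and P granule lists (0.04, adjusted p = 0.696).

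With 2 EV arrays and 0 of the 7 list tests holding with an estimated correlation, precision is limited in day 8 WT. The count was 413 and 128 without EV 1 and 2 and 136 and 145 without ash-2 RNAi 1 and 2, and without ash-2 RNAi 3 it also fell by more than 1.5-fold. An unequal variance test called 2, muscle and neuron centring (shift of the median −0.17) gave 185 (46 up), and a fit with all 23 arrays called 801.

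Day 8 glp-1 worms showed the most changes with ash-2 RNAi. K04H8.3 (4.46 ± 0.13), the saposin-like gene spp-12 (4.1 ± 0.48), the infection response gene irg-4 (4.03 ± 0.39), the lectin gene clec-265 (3.37 ± 0.30), the trypsin-like gene try-9 (3.17 ± 0.13), the heat shock gene hsp-16.41 (3.14 ± 0.31) and H04M03.3 (2.98 ± 0.20) rose (n = 3 against 3). K08D10.14 (−4.68 ± 0.36), R07C12.1 (−4.20 ± 0.42), F19C7.2 (−4.19 ± 0.29) and T05E12.3 (−4.16 ± 0.25), the claudin-like gene clc-24 (−3.77 ± 0.21), nspg-8 (−3.73 ± 0.32) and drd-10 (−3.39 ± 0.48) fell (adjusted p from 1.68e-08 to 9.40e-04 for all of these). All arrays of one group lay above all arrays of the other for each, and T05E12.3 and nspg-8 are on shared probe sets. In total 3339 probe sets passed, 1618 up and 1721 down, in 2890 genes, and the 981 that changed at least 2-fold were mostly falls (294 up, 687 down). Muscle and neuron centring shifts the median by 0.44 and turned the split to 2442 up and 465 down.

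Relative to all other genes, the respiratory chain, histone, DNA replication, oocyte and ribosomal lists lay higher in day 8 glp-1, though in each most members did not pass. Of 40 respiratory chain genes, 18 rose, 0 fell and 22 did not pass, or 26 and 0 adjusted over the list alone. Their median was 0.35 (adjusted p = 1.48e-07, adjusted p = 0.404 with an estimated correlation). Of 26 histone genes, 7 rose, 0 fell and 19 did not pass, or 10 and 1 adjusted over the list alone. The list median was 0.40 (adjusted p = 3.00e-04, adjusted p = 0.535 with an estimated correlation), led by his-62 (1.86 ± 0.15). Of 54 DNA replication genes, 10 rose, 2 fell and 42 did not pass, or 12 and 2 adjusted over the list alone. The median was 0.28 (adjusted p = 0.00638, adjusted p = 0.535 with an estimated correlation). Of 25 oocyte genes, 6 rose, 1 fell and 18 did not pass, or 7 and 2 adjusted over the list alone. Together they had a median of 0.16 (adjusted p = 0.0425, adjusted p = 0.637 with an estimated correlation), with the oocyte maturation gene oma-2 (1.76 ± 0.12). The oocyte test was lost without glp-1 EV 2 and 3 (0.18 and 0.11) and glp-1 ash-2 RNAi 3 (0.02), and the DNA replication test without ash-2 RNAi 3 (0.21). P granule genes numbered 7 and 2 up and down, or 10 and 2 adjusted over the list alone, and did not shift as a list (adjusted p = 0.0793). The probe sets of his-62 and oma-2 are shared. Of 75 ribosomal protein genes, 6 rose, 0 fell and 69 did not pass, or 1 and 0 adjusted over the list alone. As a list they had a median of 0.16 (adjusted p = 1.58e-05, adjusted p = 0.535 with an estimated correlation).

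Of 33 intestinal genes in day 8 glp-1, 0 rose, 15 fell and 18 did not pass, or 1 and 18 adjusted over the list alone. Their median was −0.40 (turning to 0.04 with muscle and neuron centring, adjusted p = 7.75e-08, adjusted p = 0.399 with an estimated correlation), with the ferritin genes ftn-1 (−1.22 ± 0.13) and ftn-2 (−1.03 ± 0.13) and the intermediate filament gene ifb-2 (−1.16 ± 0.13) among those that fell. Of 68 innate immune genes, 11 rose, 28 fell and 29 did not pass, or 13 and 36 adjusted over the list alone. The list median was −0.53 (adjusted p = 2.27e-05, adjusted p = 0.404 with an estimated correlation), with irg-3 (−1.90 ± 0.13) and clec-7 (−1.90 ± 0.17) falling and clec-4 (2.83 ± 0.12) rising. Of 73 detoxification genes, 11 rose, 19 fell and 43 did not pass, or 11 and 23 adjusted over the list alone. The median was −0.14 (turning to 0.30 with muscle and neuron centring, adjusted p = 0.00421, adjusted p = 0.399 with an estimated correlation), with the cytochrome P450 genes cyp-34A2 (−3.11 ± 0.18) and cyp-37B1 (−2.43 ± 0.20). Of 67 neuronal genes, 2 rose, 9 fell and 56 did not pass, or 2 and 9 adjusted over the list alone. Together they had a median of −0.29 (moved to 0.15 by construction with muscle and neuron centring, adjusted p = 1.91e-04, adjusted p = 0.535 with an estimated correlation). Of 55 sperm genes, 0 rose, 7 fell and 48 did not pass, or 0 and 7 adjusted over the list alone. As a list they had a median of −0.17 (turning to 0.27 with muscle and neuron centring, adjusted p = 0.00537, adjusted p = 0.535 with an estimated correlation). Of 53 moulting genes, 3 rose, 8 fell and 42 did not pass, or 4 and 11 adjusted over the list alone. Their median was −0.12 (turning to 0.32 with muscle and neuron centring and no longer passing, adjusted p = 0.00638, adjusted p = 0.535 with an estimated correlation). Lists with calls both ways did not shift: 14 and 15 of 63 fatty acid genes, 10 and 8 of 39 DAF-16 targets and 10 and 7 of 145 collagens rose and fell, or 18 and 20, 12 and 10 and 8 and 7 adjusted over the list alone. Median and mean differed in sign for fatty acid (−0.06 and 1.3e−05) and somatic gonad genes (−0.05 and 0.05), and median and test for DAF-16 targets and chaperones. The probe sets of ftn-1, ftn-2 and ifb-2 are shared. None of the 11 list tests held with an estimated correlation, shared probe sets left out gave 2108 calls, and an unequal variance test called 6.

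**Figure D3:**
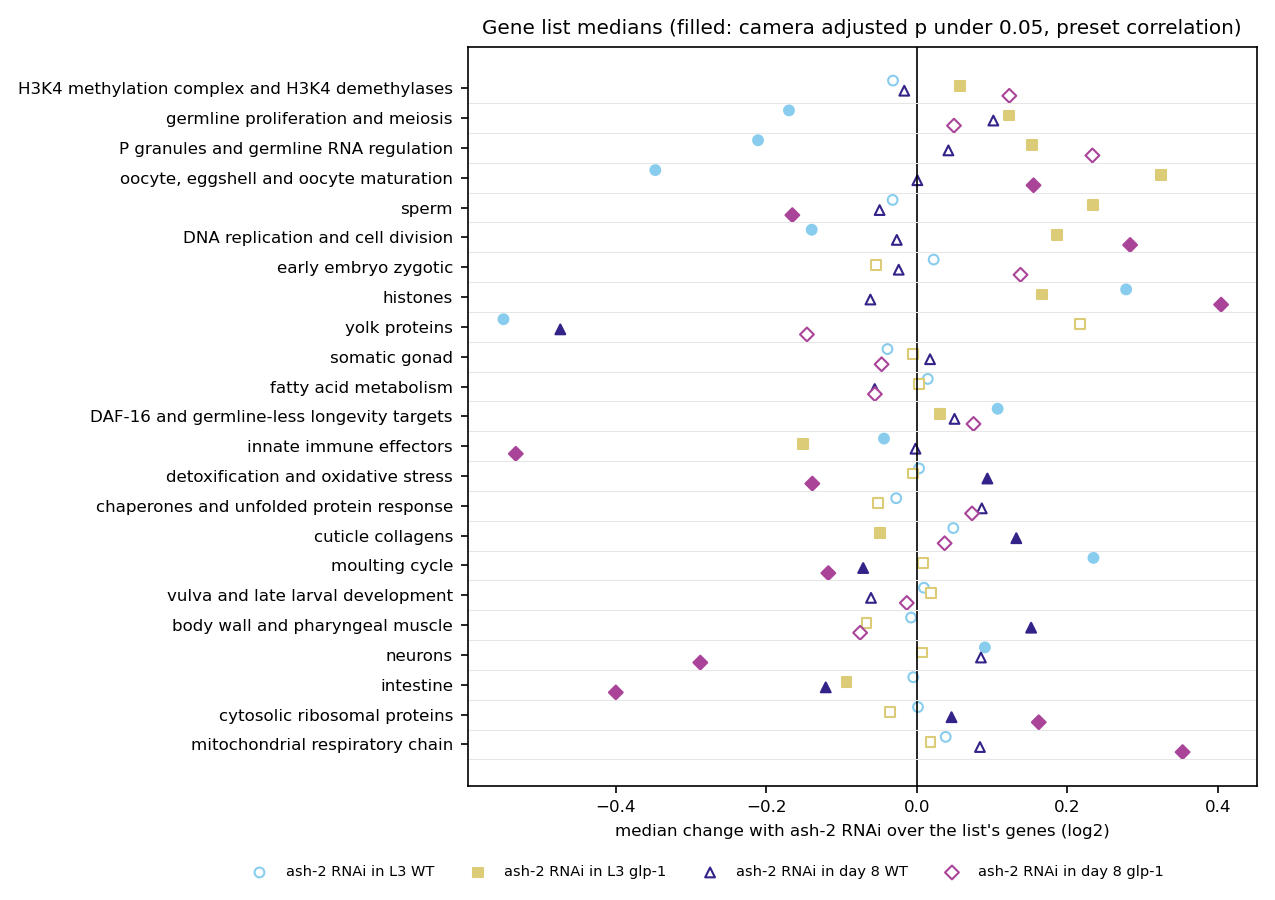
Median change (log2) of each of the 23 gene lists in the 4 ash-2 RNAi comparisons, with filled symbols where the camera test with the preset correlation passed. The respiratory chain list has a median of 0.35 and the innate immune list of −0.53 in day 8 glp-1. Several medians, that of intestine there among them, change sign with muscle and neuron centring.

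At day 8 the response to ash-2 RNAi differed between genotypes for 902 probe sets in 808 genes. The monooxygenase gene fmo-2 fell in WT with a level of 9.66 under EV and lay at 5.02 and 4.78 in the glp-1 groups, a difference of −4.84 ± 0.28 (WT minus glp-1, adjusted p = 2.30e-05). T22F3.11 (−3.98 ± 0.22) and C23G10.11 (−3.34 ± 0.35) likewise differed through the 2 day 8 WT EV arrays, where they were high. K04H8.3 (−4.24 ± 0.19), irg-4 (−3.47 ± 0.59), H04M03.3 (−3.0 ± 0.30) and try-9 (−2.90 ± 0.19) rose more in glp-1, and K08D10.14 (3.59 ± 0.54), clc-24 (3.48 ± 0.32), F18E3.11 (3.31 ± 0.50) and T16G1.6 (3.14 ± 0.35), the neuropeptide-like gene nlp-25 (3.10 ± 0.43) and ugt-9 (3.08 ± 0.46) fell more in glp-1 (largest adjusted p = 0.00956). The 3 shared ash-2 probe sets rose less in WT (up to −3.27), and 175434 fell more there (−1.42 ± 0.21, adjusted p = 0.00499), but its EV level was 6.89 in WT and 5.33 in glp-1, which left less room to fall. Positive differences numbered 525 and negative ones 377, but 82 and 616 with muscle and neuron centring, which shifts the median by −0.61.

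None of the 12 list tests of this day 8 difference held with an estimated correlation (adjusted p from 0.0987 to 0.637). Lists on the positive side, all turning negative with muscle and neuron centring, were detoxification (14 and 2 of 73 positive and negative, median 0.23, adjusted p = 7.40e-06), muscle (3 and 0 of 44, median 0.36, adjusted p = 4.92e-05), neuronal (1 and 0 of 67, median 0.39, adjusted p = 4.92e-05), innate immune (9 and 4 of 68, median 0.28, adjusted p = 0.00310), intestinal (5 and 1 of 33, median 0.31, adjusted p = 0.00242), collagen (6 and 2 of 145, median 0.09, adjusted p = 0.0199) and sperm genes (1 and 0 of 55, median 0.15, adjusted p = 0.0224). The collagen test no longer passed with that centring (adjusted p = 0.0562). Adjusted over the list alone these counts were 24 and 5, 8 and 0, 6 and 0, 21 and 6, 8 and 1, 7 and 2 and 1 and 0. Histone (0 and 6 of 26, median −0.52, adjusted p = 2.06e-05), respiratory chain (0 and 1 of 40, median −0.25, adjusted p = 1.36e-04), DNA replication (0 and 3 of 54, median −0.29, adjusted p = 0.00444), oocyte (1 and 2 of 25, median −0.31, adjusted p = 0.0241) and ribosomal genes (0 and 1 of 75, median −0.11, adjusted p = 0.0106) lay on the negative side, with 0 and 8, 0 and 0, 1 and 5, 1 and 2 and 0 and 1 adjusted over the list alone. Without WT EV 1 the oocyte (−0.16), DNA replication (−0.23), collagen (0.07) and ribosomal tests (−0.10) were lost. The oocyte test was also lost without glp-1 ash-2 RNAi 3 (−0.19), the ribosomal test without glp-1 ash-2 RNAi 1 (−0.07), and the collagen test without WT ash-2 RNAi 1 (0.07), glp-1 EV 3 (0.0060) or glp-1 ash-2 RNAi 3 (0.07). The sperm test was lost without WT EV 2 (0.04), WT ash-2 RNAi 2 (0.10), glp-1 EV 1 (0.12) and glp-1 ash-2 RNAi 2 (0.13). Muscle genes had 0.14 without glp-1 EV 1, and histone and intestinal genes −0.21 and 0.18 without WT EV 2. The DAF-16 target list gave 7 and 4 of 39, with median 0.16 and mean −0.03.

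The count of differences was 385 without WT EV 2 and 451, 410 and 550 without WT ash-2 RNAi 1, 2 and 3, and 2465 with all 23 arrays in the fit. Between the separate day 8 comparisons, 50 probe sets rose in both genotypes against 9.33 by chance, 87 fell in both against 15.3, and 19 moved in opposite directions against 24.3 (r = 0.248 and rho = 0.138 across probe sets, which are not independent replicates).

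**Figure D4:**
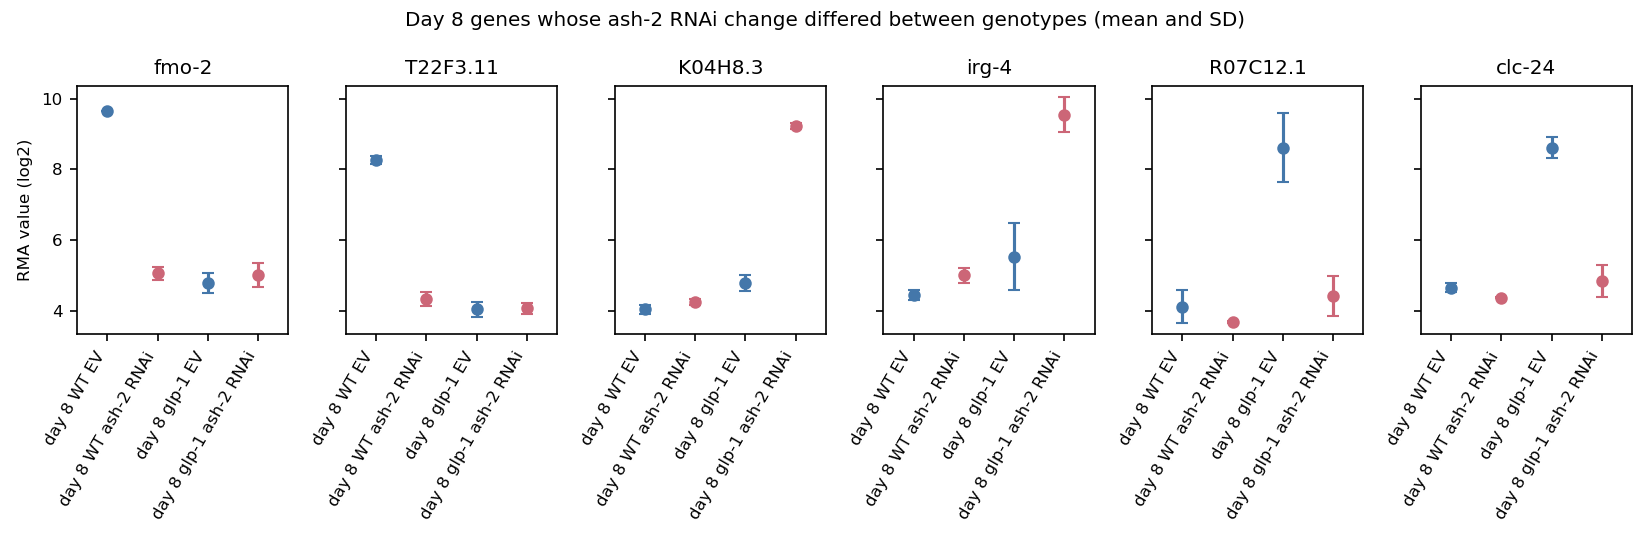
Mean RMA value (log2, bars for SD, 2 arrays for WT EV and 3 for the other groups) of fmo-2, T22F3.11, K04H8.3, irg-4, R07C12.1 and clc-24 in the 4 day 8 groups. The gene fmo-2 is at 9.66 in the 2 WT EV arrays and at 4.78 to 5.06 in the other groups.

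A small set of genes passed in the same direction in all 4 ash-2 comparisons. Probe sets that rose in each numbered 8: the 3 of ash-2, those of clec-174, irg-5, hsp-16.2 and hsp-16.41, and 1 that names several genes. Those that fell in each numbered 2. They were asah-2, an acid ceramidase gene chosen after its values were seen (−0.52 and −0.55 in L3 WT and glp-1, −1.25 and −1.72 on day 8, with adjusted p = 0.0470 in L3 WT), and F19C7.2 (−1.21 and −1.16 at L3, −1.54 and −4.19 on day 8, with adjusted p = 0.0436 in day 8 WT). Between ages, 11 probe sets rose and 3 fell at both in WT, against 0.283 and 0.223 by chance. In glp-1, 35 rose and 37 fell at both ages, against 8.11 and 5.11, and 6 moved in opposite directions, against 13.4.

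Genes that need the germline were followed as a set, taken from the other age so that no array is shared. The 4240 probe sets that were at least 2-fold lower in glp-1 on day 8 had a median of 0.09 with ash-2 RNAi in L3 glp-1, where 31 rose and 1 fell (camera p = 1.28e-12, and p = 0.0346 with an estimated correlation), a direction that turned to −0.06 with muscle and neuron centring. In L3 WT their median was −0.05 (p = 9.82e-07, and p = 0.118 with an estimated correlation), although 6 rose and 0 fell. The 2125 probe sets taken from L3 had a median of 0.15 in day 8 glp-1, with 282 up and 35 down (p = 3.65e-06, and p = 0.00850 with an estimated correlation), and of 0.02 in day 8 WT (p = 0.234), where 1 rose and 6 fell.

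**Figure D5:**
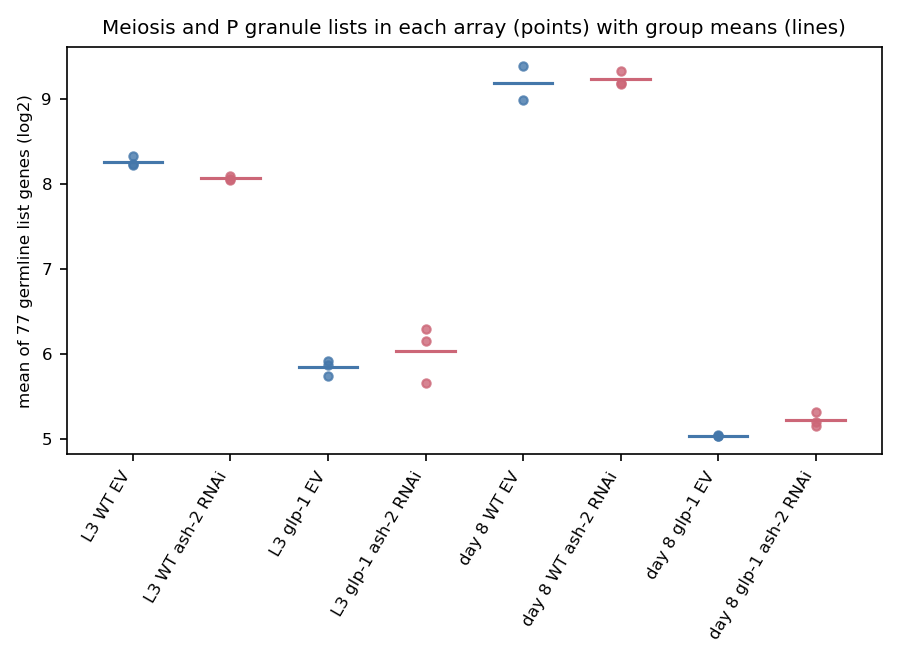
Mean RMA value (log2) of the 77 genes of the meiosis and P granule lists, with a point for each array and a line for each group mean. The groups differ by −0.19 in L3 WT and by 0.18 in day 8 glp-1 without overlap, and overlap in L3 glp-1.

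In WT the response to ash-2 RNAi also changed with age, for 349 probe sets (121 more positive on day 8, 228 more negative). The saposin-like gene spp-12 (4.66 ± 0.55), srlf-30 (2.07 ± 0.25), the chaperone gene hsp-70 (2.05 ± 0.34) and the collagen genes col-140 (2.02 ± 0.36) and col-80 (1.70 ± 0.30) were more positive on day 8 than at L3. The monooxygenase gene fmo-2 (−5.03 ± 0.28), adh-1 (−3.83 ± 0.56), T22F3.11 (−3.82 ± 0.21), acs-2 (−2.22 ± 0.44), hacd-1 (−1.75 ± 0.24) and icl-1 (−1.44 ± 0.17) and the ash-2 probe set 175434 (−1.49 ± 0.18) were more negative (largest adjusted p = 0.0102 among these genes), with hsp-70, col-140 and icl-1 on shared probe sets. None of the 12 list tests held with an estimated correlation (adjusted p from 0.207 to 0.727). Of 145 collagens 13 were more positive, or 18 adjusted over the list alone. The list median was 0.10 (adjusted p = 1.35e-04). Of 44 muscle genes 5 were, or 11 (median 0.15, adjusted p = 2.79e-07), and of 73 detoxification genes 7, or 15 (median 0.09, adjusted p = 1.35e-04). Of 53 moulting genes 5 were more negative, or 10 adjusted over the list alone. The median was −0.31 (adjusted p = 3.40e-09). Of 26 histone genes 1 was, or 8 (median −0.32, adjusted p = 4.75e-08). Intestinal (median −0.12, adjusted p = 0.0117) and early embryo genes (median −0.10, adjusted p = 0.0388) were also more negative. Meiosis (median 0.26, adjusted p = 2.47e-04), P granule (median 0.26, adjusted p = 0.00871), oocyte (median 0.37, adjusted p = 0.0125) and chaperone genes (median 0.09, adjusted p = 0.0177) were more positive, as were ribosomal genes (median 0.04, adjusted p = 0.0177), which turned to −0.01 with muscle and neuron centring and no longer passed (adjusted p = 0.245).

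In this contrast the collagen median was 0.0060 without L3 WT ash-2 RNAi 3. Leaving out day 8 WT EV 2 ended the meiosis (0.13) and histone tests (−0.09), and leaving out day 8 WT EV 1 ended the intestine test (−0.02). Oocyte genes lost theirs without L3 WT EV 2 (0.33), L3 WT ash-2 RNAi 3 (0.27) and day 8 WT EV 2 (0.28). P granule genes lost theirs without day 8 WT EV 2 (0.01) and day 8 WT ash-2 RNAi 3 (0.15). Chaperones did without L3 WT EV 3 (0.07), L3 WT ash-2 RNAi 2 (0.07), day 8 WT EV 2 (−0.03) and day 8 WT ash-2 RNAi 3 (0.01), early embryo genes without L3 WT EV 2 (−0.07), L3 WT ash-2 RNAi 2 and 3 (−0.09 and −0.13), day 8 WT EV 2 (−0.00065) and day 8 WT ash-2 RNAi 1 (−0.13) and ribosomal genes without L3 WT EV 2 and 3 (0.04 and 0.03), L3 WT ash-2 RNAi 2 (0.03), day 8 WT EV 2 (0.04) and day 8 WT ash-2 RNAi 1 (0.04). The count was 229 and 207 without L3 WT EV 1 and 2, 588 and 197 without day 8 WT EV 1 and 2, and 83 (27 up, 56 down) with muscle and neuron centring.

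Under EV at L3, the glp-1 mutant had less of most germline transcripts. The RNA regulator gene gld-1 (−5.36 ± 0.45), C48B4.10 (−5.48 ± 0.14), the polo-like kinase gene plk-3 (−5.1 ± 0.52), the translation factor gene iff-1 (−5.02 ± 0.32), the meiotic axis gene htp-1 (−4.77 ± 0.17) and the P granule helicase gene glh-1 (−4.58 ± 0.15) were lower in glp-1 (n = 3 against 3, largest adjusted p = 2.56e-06). The lectin gene clec-47 (2.94 ± 0.19), the infection response gene irg-1 (2.09 ± 0.13) and the heat shock genes hsp-16.41 (1.77 ± 0.16) and hsp-16.2 (1.34 ± 0.12) were higher. The probe sets of plk-3, glh-1 and vit-5 are shared. The meiosis, P granule, DAF-16 target, innate immune and neuron tests held with an estimated correlation and the other 11 did not (adjusted p from 0.0551 to 0.372 with an estimated correlation). Of 36 meiosis genes 35 fell (median −2.40, adjusted p = 7.39e-22). Of 41 P granule genes 39 did (median −2.58, adjusted p = 7.39e-22). Of 54 DNA replication genes 50 did (median −1.87, adjusted p = 8.56e-23). Of 25 oocyte genes 19 did (median −2.87, adjusted p = 4.16e-08) and of 55 sperm genes 52, with 2 up (median −1.06, adjusted p = 3.13e-18). Of 16 H3K4 genes 9 fell and 4 rose (median −0.39, adjusted p = 0.0307), with the methyltransferase gene set-2 (−1.59 ± 0.12) among the falls. Adjusted over the list alone, 0 and 35, 0 and 39, 0 and 50, 0 and 19, 2 and 52 and 5 and 9 of these lists rose and fell. Higher in glp-1, all with medians that turned negative with muscle and neuron centring, were neuronal (55 of 67, median 0.63, adjusted p = 6.50e-09), muscle (40 of 44, median 0.56, adjusted p = 6.17e-07), innate immune (47 of 68, median 0.51, adjusted p = 6.22e-07), moulting (48 of 53, median 0.74, adjusted p = 1.89e-07), DAF-16 target (22 of 39, median 0.39, adjusted p = 8.04e-04), detoxification (median 0.43, adjusted p = 5.23e-05), intestinal (median 0.37, adjusted p = 9.33e-05), collagen (median 0.30, adjusted p = 3.35e-05), fatty acid (median 0.32, adjusted p = 0.00222) and vulva genes (median 0.47, adjusted p = 0.0270). The fatty acid test no longer passed with that centring (adjusted p = 0.0669). The yolk protein genes, from vit-1 (−0.15 ± 0.30) to vit-5 (−0.05 ± 0.21), did not pass. Of 12521 probe sets, 7538 rose and 4983 fell, against 359 and 17459 with muscle and neuron centring (shift −0.74) and 10728 and 4493 with median centring (shift 0.10).

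On day 8 eggshell and oocyte genes were among the largest differences between genotypes. The eggshell gene cpg-2 (−8.91 ± 0.46), the small heat shock gene sip-1 (−8.70 ± 0.43), the RNA-binding gene spn-4 (−8.16 ± 0.24), gld-1 (−7.60 ± 0.18) and the oocyte gene oma-2 (−6.96 ± 0.13) were lower in glp-1 (n = 3 against 2). The cytochrome P450 gene cyp-35B1 (6.33 ± 0.19), the dehydrogenase gene dhs-26 (6.02 ± 0.37), ugt-63 (5.89 ± 0.30) and the ferritin gene ftn-1 (4.36 ± 0.14) were higher (largest adjusted p = 6.66e-08 for all of these), and those of cpg-2, oma-2, ftn-1 and vit-5 are shared probe sets. The yolk, sperm, muscle, neuron, collagen, ribosomal and respiratory chain tests were lost with an estimated correlation (adjusted p from 0.0561 to 0.350 with an estimated correlation). All 5 yolk protein genes rose in glp-1, from vit-5 (0.78 ± 0.12) to vit-1 (3.72 ± 0.31), a direction that turned with muscle and neuron centring for all but vit-1 (median 0.96, adjusted p = 0.0153), and with which the list no longer passed (adjusted p = 0.0616). Under EV in glp-1 the values of vit-4, vit-5 and vit-6 lie within 0.24 of the highest of each array, so saturation is not excluded and the sizes of their changes here and with age are uncertain. Of 41 P granule genes 41 fell (median −4.61, adjusted p = 7.39e-19). Of 36 meiosis genes 35 did (median −3.65, adjusted p = 3.91e-16). Of 25 oocyte genes 23 did (median −6.29, adjusted p = 1.57e-12). Of 54 DNA replication genes 52 did (median −4.61, adjusted p = 1.72e-22) and of 16 H3K4 genes 13 (median −1.81, adjusted p = 2.49e-05), with 41, 35, 23, 52 and 14 adjusted over the list alone. Ribosomal (71 of 75 down, median −0.74, adjusted p = 6.31e-12) and respiratory chain genes (24 of 40, median −0.44, adjusted p = 0.00125) were lower too. Higher in glp-1 were DAF-16 targets (31 of 39, median 2.58, adjusted p = 2.75e-09) and innate immune genes (59 of 68, median 2.32, adjusted p = 1.29e-12). Also higher, but turning negative with muscle and neuron centring, were muscle (median 1.80, adjusted p = 6.18e-10), intestinal (median 1.80, adjusted p = 3.83e-11), fatty acid (median 1.63, adjusted p = 3.81e-10), neuronal (median 1.67, adjusted p = 2.73e-07), detoxification (median 1.39, adjusted p = 2.54e-08), collagen (median 0.76, adjusted p = 1.69e-08) and sperm genes (median 0.45, adjusted p = 0.0235). The sperm test no longer passed with that centring (adjusted p = 0.0858). The DAF-16 target list includes sip-1, which fell. Of 12371 probe sets, 6376 rose and 5995 fell, or 1228 and 18926 with muscle and neuron centring (shift −2.06).

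From L3 to day 8 in WT under EV, cuticle and sperm transcripts fell and oocyte transcripts rose. The collagen genes col-139 (−8.80 ± 0.25) and col-129 (−8.75 ± 0.20) and the sperm protein genes msp-45 (−8.61 ± 0.23) and msd-4 (−7.32 ± 0.18) fell, and the caveolin gene cav-1 (7.03 ± 0.60), skr-13 (5.61 ± 0.19) and the chitinase gene cht-1 (5.27 ± 0.30) rose, all on shared probe sets (n = 2 against 3, largest adjusted p = 1.69e-09). The P granule, oocyte, detoxification, neuron, intestine, ribosomal and respiratory chain tests were lost with an estimated correlation (adjusted p from 0.0649 to 0.346 with an estimated correlation). Of 145 collagens 134 fell (median −3.92, adjusted p = 1.44e-23). Of 55 sperm genes 52 did (median −5.76, adjusted p = 3.06e-16). Of 44 muscle genes 43 did (median −3.15, adjusted p = 1.51e-13) and of 53 moulting genes 50 (median −2.81, adjusted p = 2.85e-12). Of 25 oocyte genes 20 rose (median 1.82, adjusted p = 1.06e-10). Of 54 DNA replication genes 48 did (median 1.07, adjusted p = 1.76e-14). Of 41 P granule genes 32 did (median 1.18, adjusted p = 2.80e-10). Of 36 meiosis genes 22 did (median 0.72, adjusted p = 3.34e-07) and of 16 H3K4 genes 15 (median 1.00, adjusted p = 4.75e-06). Lower, but with medians turning positive with muscle and neuron centring, were fatty acid (median −1.20, adjusted p = 0.00268), detoxification (median −0.94, adjusted p = 9.63e-04), neuronal (median −1.46, adjusted p = 2.31e-05), intestinal (median −1.20, adjusted p = 0.00428), ribosomal (median −0.52, adjusted p = 1.61e-05) and respiratory chain genes (median −1.08, adjusted p = 2.59e-06). The ribosomal median turned positive with quantile normalization and median centring as well, and its test no longer passed with any of the 3 (adjusted p = 0.105, 0.0939 and 0.280). The respiratory chain test no longer passed with muscle and neuron centring (adjusted p = 0.280). Of 15447 probe sets 4920 rose and 10527 fell, a balance that turned to 8074 and 5866 with quantile normalization (shift 0.36), 15251 and 4083 with median centring (shift 0.97) and 20075 and 1141 with muscle and neuron centring (shift 2.57).

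In glp-1 the same collagen and sperm lists fell with age. col-109 (−8.97 ± 0.12), the cuticle genes bli-1 (−8.63 ± 0.19) and dpy-5 (−8.15 ± 0.19) and the sperm gene msp-49 (−5.96 ± 0.16) fell, and cyp-35B1 (7.56 ± 0.13), the caenacin gene cnc-7 (7.43 ± 0.23), the lysozyme gene ilys-3 (6.78 ± 0.35) and the ferritin gene ftn-1 (4.49 ± 0.14) rose (n = 3 against 3, largest adjusted p = 5.54e-13), with bli-1, dpy-5, msp-49, cnc-7 and ftn-1 on shared probe sets. The DAF-16 target and fatty acid tests held with an estimated correlation and the other 11 did not (adjusted p from 0.0611 to 0.308 with an estimated correlation). Of 145 collagens 131 fell (median −2.72, adjusted p = 1.39e-17). Of 55 sperm genes 51 did (median −3.41, adjusted p = 2.54e-10). Of 53 moulting genes 46 did (median −3.33, adjusted p = 1.23e-10). Of 44 muscle genes 43 did (median −1.71, adjusted p = 5.12e-09) and of 54 DNA replication genes 45 (median −1.53, adjusted p = 1.76e-04). All 75 ribosomal genes fell (median −1.21, adjusted p = 3.95e-16), although their median was 0.05 with muscle and neuron centring, and 39 of 40 respiratory chain genes did (median −1.56, adjusted p = 2.44e-10). Of 39 DAF-16 targets 25 rose and 11 fell (median 0.79, adjusted p = 3.77e-10). Of 5 yolk protein genes 5 rose (median 1.11, adjusted p = 0.00108) and of 68 innate immune genes 35 rose and 22 fell (median 0.52, adjusted p = 4.15e-08). Relative to other genes, fatty acid (median 0.13, adjusted p = 1.91e-05) and intestinal genes (median 0.09, adjusted p = 1.76e-04) were higher. The detoxification test pointed up with a negative median that turned positive with each of the 3 scalings and a mean of 0.11 (median −0.18, adjusted p = 0.0136), and it no longer passed with any of these scalings (adjusted p = 0.131, 0.383 and 0.154). Of 16106 probe sets 3708 rose and 12398 fell, or 7236 and 6265 with quantile normalization (shift 0.40), 13171 and 4411 with median centring (shift 0.79) and 15931 and 2141 with muscle and neuron centring (shift 1.26). The medians of L3 and day 8 arrays differ, and array batch cannot be told apart from age here.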

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

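The tests of explanations below were chosen after the patterns were seen, and those on the ash-2 transcript, double-stranded RNA and germ cell content after the tested values too, while the tests by other splits were chosen before. The results listed here stand out because the effect of ash-2 RNAi differed between genotypes or ages by a test of the difference itself.

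At L3 the lists that differed (median change in WT minus that in glp-1) were meiosis −0.29, P granules −0.39, oocyte −0.70, sperm −0.28, DNA replication −0.27, yolk proteins −0.79, histones 0.13, DAF-16 targets 0.10, collagens 0.10, moulting 0.22 and neurons 0.11. Of these 11 tests 0 held with an estimated correlation (adjusted p from 0.284 to 0.657), and those of histones, DAF-16 targets, collagens and neurons were each lost on leaving out single arrays. Without glp-1 EV replicate 3 the yolk, oocyte and moulting medians were −0.45, −0.41 and 0.11. On day 8 902 probe sets differed. Among genes these were R07C12.1 3.77 (3.43 without WT EV replicate 2, where it no longer passed), K08D10.14 3.59, clc-24 3.48, F57H12.6 3.33, F18E3.11 3.31, T16G1.6 3.14, nlp-25 3.10, ugt-9 3.08, fmo-2 −4.84, K04H8.3 −4.24, T22F3.11 −3.98, irg-4 −3.47, C23G10.11 −3.34, ash-2 −3.27, H04M03.3 −3.0 and try-9 −2.90. Among lists they were oocyte −0.31, sperm 0.15, DNA replication −0.29, histones −0.52, innate immunity 0.28, detoxification 0.23, collagens 0.086, muscle 0.36, neurons 0.39, intestine 0.31, ribosomal proteins −0.11 and respiratory chain −0.25. Of these 12 tests 0 held with an estimated correlation (adjusted p from 0.0987 to 0.637), the 7 positive medians turned negative with muscle and neuron centring, and the oocyte, sperm, DNA replication, collagen and ribosomal tests were each lost on leaving out single arrays. The muscle median was 0.14 without glp-1 EV replicate 1 and the histone and intestine medians −0.21 and 0.18 without WT EV replicate 2.

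With age in WT 349 probe sets differed (change on day 8 minus that at L3), among them spp-12 4.66, C17H12.6 2.53, col-101 2.37, col-143 2.15, ugt-63 2.11, lys-10 2.07, srlf-30 2.07, hsp-70 2.05, fmo-2 −5.03, adh-1 −3.83, T22F3.11 −3.82, C23G10.11 −3.01, ilys-5 −2.71, best-1 −2.47, C35C5.8 −2.29 and acs-2 −2.22. On leaving out single arrays col-101 (1.92 to 2.67 without each of 7 arrays), col-143 (1.76 to 2.43 without each of 7) and ugt-63 (1.55 without 1) no longer passed. The lists were meiosis 0.26, P granules 0.26, oocyte 0.37, early embryo −0.10, histones −0.32, detoxification 0.087, chaperones 0.092, collagens 0.10, moulting −0.31, muscle 0.15, intestine −0.12 and ribosomal proteins 0.042. Of these 12 tests 0 held with an estimated correlation (adjusted p from 0.207 to 0.727). The ribosomal median turned negative with muscle and neuron centring, and the meiosis, P granule, oocyte, early embryo, histone, chaperone, intestine and ribosomal tests were each lost on leaving out single arrays.

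Of the ash-2 probe sets 3 rose with RNAi, and 175434 lay lower but passed only in day 8 WT. A rise of the whole transcript is argued against, since the highest upper 95% limit of the change of 175434 over the 4 comparisons was −0.0207. Double-stranded RNA from the RNAi clone may bind to the 3 probe sets, whose smallest rise was 4.54, but the cloned sequence is not given, so this stays open. No biological explanation was tested.

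The meiosis, P granule, oocyte and DNA replication lists lay lower with ash-2 RNAi in L3 WT and higher in L3 glp-1. Germ cell content that differs between glp-1 arrays whatever the RNAi may account for the glp-1 side, where the shift was 0.792 within-group SDs and 6 of 9 pairs lay higher, against −4.19 SDs and 0 of 9 pairs in WT. On day 8 in glp-1 it was 3.03 SDs (9 of 9 pairs higher). Slower development of the WT worms stays open, as its test cannot decide. Across genes (not independent replicates) the L3 WT change correlated at −0.111 with age in glp-1. There the meiosis and P granule mean fell (5.84 to 5.04), while in WT it rose (8.27 to 9.20). An effect of ash-2 on germ cells, which the design names through the genotypes, was not tested apart from these.

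More probe sets changed with ash-2 RNAi in day 8 glp-1 (3339) than in day 8 WT (331). The array fewer in the WT EV group is argued against as the whole cause, since the glp-1 count was at least 2523 with 1 glp-1 EV array left out, and so are the 2 glp-1 arrays that stand apart, without which it was 2752. Dilution of somatic changes by germline RNA in WT stays open. The noise-corrected spread of changes of intestine, innate immune and detoxification genes in WT was 0.675 of that in glp-1 (95% interval 0.519 to 0.846 over 10000 resamples of genes, not arrays), but their levels under EV lie lower in WT (median glp-1 minus WT 2.05), where the floor of the arrays narrows changes too. A difference between the genotypes in their response may remain, as a hypothesis.

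Other splits of the same arrays were counted. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real splits called 74, 180, 3339, 12521 and 16106 probe sets (ash-2 RNAi in L3 WT, L3 glp-1 and day 8 glp-1, glp-1 against WT at L3, age in glp-1), where the highest other split called 0, 54, 1, 0 and 1. For gene lists the real splits called 10, 11, 11, 16 and 13 and the highest other 10, 14, 8, 17 and 15. In L3 WT the other splits that part 3 same-numbered pairs called 0 probe sets each and 6, 7 and 10 lists. Pairing by number is not clearly shown there. For lists in the L3 interaction, chance is not excluded: 8 of 100 splits called at least the real 11, with a highest other of 12. Its count of probe sets tests nothing, since the real count is 0. The highest other count, 283, came from swapping EV and ash-2 RNAi in glp-1 alone, which adds the RNAi changes of both genotypes.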

How the results depend on the processing

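Number of arrays, scale between arrays and correlation between genes limit these results. The arrays per group (2 or 3) limit precision: several counts of probe sets move by more than 1.5-fold with array weights or without 1 array, while directions of single genes hold. Directions of many lists rest on the scale, since centring on muscle and neuron genes turns them, also where the median is far from 0. All list tests of the ash-2 comparisons other than 2 in L3 WT rest on the preset correlation. Of the list tests, 145 kept their side of the threshold with an estimated correlation and 108 were lost, and on leaving out 1 array 1665 were kept, 66 gained, 85 lost and 1 reversed. Of named genes with an unequal variance test 505 kept theirs and 300 lost it. With muscle and neuron centring, 830 of 1065 were kept, 60 reversed, 23 gained and the others lost. Except where the text says so, the cause was not tested.

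With 1 array left out, counts of probe sets ranged from 39 to 50 in L3 WT (74 with all), 47 to 307 in L3 glp-1 (180), 0 to 62 for the L3 interaction (0), 128 to 413 in day 8 WT (331), 385 to 960 for the day 8 interaction (902) and 197 to 588 for the RNAi by age interaction (349). Numbers of lists ranged from 6 to 14 in L3 glp-1, 7 to 11 for the L3 interaction, 6 to 11 in day 8 WT and 6 to 14 for the RNAi by age interaction. The 175434 change in day 8 glp-1 ranged from −0.51 to −0.28 and passed in only 1 (−0.51). P granule genes in the RNAi by age interaction had a median from 0.0084 to 0.49, and without day 8 WT EV replicate 2 (0.0084) their test pointed the other way, since it compares them with all other genes.

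With an estimated correlation 2 lists passed in L3 WT, 5 for glp-1 against WT at L3, 10 for that on day 8, 8 for age in WT and 2 for age in glp-1. 0 passed in L3 glp-1, day 8 WT, day 8 glp-1, the interactions at L3 and day 8 and the RNAi by age interaction. The L3 WT median of germline-dependent probe sets (−0.047) no longer passed.

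With an unequal variance test, whose variance comes from 2 or 3 arrays per group alone, 0 probe sets passed in L3 WT, 0 in L3 glp-1, 2 in day 8 WT, 6 in day 8 glp-1, 7165 for glp-1 against WT at L3, 5092 for that on day 8 and 7212 for age in WT. The ash-2 changes of 5.91, 6.54 and 6.93 in L3 WT, 6.45, 6.48 and 6.91 in L3 glp-1, 4.54, 4.70, 5.01 and −1.82 in day 8 WT and 7.97 and 8.29 in day 8 glp-1 then no longer passed.

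With array weights 306 probe sets passed in L3 WT, 72 in L3 glp-1, 548 in day 8 WT and 582 for the RNAi by age interaction, and ash-2 probe set 175434 passed in L3 WT (−0.34). With all 23 arrays in the fit 34 passed in L3 WT, 110 in L3 glp-1, 801 in day 8 WT, 5296 in day 8 glp-1 (with 175434 at −0.40) and 2465 for the day 8 interaction. With only the groups compared, 168 passed in L3 WT, 25 in L3 glp-1 and 1980 in day 8 glp-1.

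Without shared probe sets, where fewer are tested, 33 passed in L3 WT, 207 in day 8 WT, 2108 in day 8 glp-1, 7998 and 7692 for glp-1 against WT at L3 and day 8 and 203 for the RNAi by age interaction. With a 1.5-fold minimum, which can only remove calls, 99 passed in L3 glp-1 and 7213 for glp-1 against WT at L3. Without dim probe sets 10633 passed for age in glp-1. At an unadjusted p of 0.01 the overlaps of same-direction probe sets were 157 between genotypes at L3, 262 between genotypes on day 8, 74 between ages in WT and 329 between ages in glp-1.

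With muscle and neuron centring 185 probe sets passed in day 8 WT, 20154 for glp-1 against WT on day 8 and 83 for the RNAi by age interaction. This centring reversed pat-10 (0.0012) and unc-52 (0.0097) in day 8 glp-1, sqv-4 in the day 8 interaction (−0.013), vit-4 (−1.1), vit-2 (−0.26), vit-5 (−1.28) and vit-6 (−1.17) in glp-1 against WT on day 8, and germline-dependent probe sets in L3 glp-1 (−0.059). Ribosomal protein genes with age in WT reversed to 0.15 with quantile normalization, 0.45 with median centring and 2.05 with muscle and neuron centring.

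Replicate number was also tried as a block, though pairing by number is not clearly shown in L3 WT. With the block in the fit of all L3 arrays the L3 WT count was 95, and day 8 WT, where pairing is not shown either, gave 215. With the 6 L3 WT arrays alone, an alternative chosen after seeing the data, the block gave 711 probe sets, with 175434 (−0.33) passing.

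Further alternatives chosen after seeing the data were the mean of the meiosis and P granule lists as a covariate, the H3K4 list without ash-2 and leaving out arrays that stand apart. With the covariate 46 probe sets and 6 lists passed in L3 WT, 7 lists in L3 glp-1 and 1 probe set for the L3 interaction. By construction it removes what these lists share. It reversed medians and tests of oocyte genes in L3 WT (0.084), L3 glp-1 (−0.032) and the L3 interaction (0.15) and of P granule genes in the L3 interaction (0.035), while for P granule genes in L3 glp-1 only the test turned and the median shrank to 0.013. Without ash-2 as a member the H3K4 list did not pass in L3 glp-1 (0.042). Without the arrays that stand apart 7 lists passed in day 8 glp-1.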

Other observations

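The test of a return towards the WT profile was chosen after its result was seen, and so were the gene name classes and the chromosomes described here. Genes on the X chromosome lay higher in glp-1 than in WT under EV on the deposited scale. Their median was 0.40 at L3, with 1445 of 2353 up and 39 down (adjusted p = 0.0230 with an estimated correlation), and 0.37 on day 8, with 1111 up and 235 down (adjusted p = 0.00541 with an estimated correlation). These directions rest on the scale: with muscle and neuron centring, tried after seeing the data, the medians were −0.34 (59 up, 1321 down) and −1.69 (196 up, 1717 down). X genes then still lay higher relative to other genes with the preset correlation (adjusted p = 5.53e-12 and 2.07e-05), but not with an estimated correlation (adjusted p = 0.415 and 0.974).

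Among classes of at least 15 genes that share a name root, mitochondrial ribosomal proteins rose with ash-2 RNAi in day 8 glp-1, 17 of 34 of the large subunit (mrpl, median 0.52) and 13 of 25 of the small one (mrps, median 0.61), with 0 falling. These classes had an adjusted p of 9.98e-08 and 2.82e-06, but adjusted p = 0.720 with an estimated correlation.

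In L3 WT EV the yolk protein genes lay at or above percentile 96.7 of each array. In WT EV the values at L3 and on day 8 were 12.13 and 9.18 for vit-1, 11.44 and 11.09 for vit-2, 13.25 and 13.40 for vit-4, 13.42 and 13.71 for vit-5 and 13.46 and 13.41 for vit-6, though the ages look to have been normalized apart. Yolk proteins are made by adults, so these values argue against all these worms being at L3, though stage was not tested.

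Where ash-2 RNAi changed expression in day 8 glp-1, it may have moved it towards the WT profile. Across 17116 genes, which are not independent replicates, the change correlated at −0.250 with the difference between glp-1 and WT at L3, from arrays the comparison does not share. The same correlation was 0.194 for L3 WT and −0.300 for L3 glp-1, each with the day 8 difference, and −0.0179 for day 8 WT. With the day 8 difference, which shares the glp-1 EV arrays, it was −0.395, where noise from the shared arrays alone gave −0.448 in 100 simulations. The covariance was −0.340, beyond the simulated −0.0181 (−0.0195 to −0.0161). This is a hypothesis found and tested on the same data.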
